A study of Homo sapiens with 8 samples.

How the data were processed

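The 8 arrays were 2-colour hybridizations of RNA from the prostate cancer cell line DU 145. Per the labels, untreated RNA was labelled with Cy5 and emetine-treated RNA with Cy3, while channel 1 is listed as emetine-treated and channel 2 as untreated. No dye swap is among the samples. The ratio is described there as tumour over reference, without a statement of which channel each was. For the self-self array, the title and both source names give emetine-treated RNA in both channels, whereas its description repeats the sentence on untreated RNA in Cy5. The design was read from the title and source names.

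Per the labels, the authors subtracted the background, divided the intensities of the channels at each spot, and normalized within each slide by ratio statistics on housekeeping genes. They state that ratios with a quality value below 0.5 were set aside. The deposited table held a value in every cell and no quality column. The deposited values were log2 ratios: 100% of the values below a ratio of 1 were log2 of whole multiples of 0.0001, within a tolerance of 0.01 of that step. The log base was found from the values, and the direction stayed unstated. The medians of the deposited columns were 0.012 on the self-self array, 0.0050 at 0 min, 0.051 at 10 min, -0.0088 at 30 min, 0.0027 at 60 min, 0.091 in the repeated column and 0.028 at 480 min, so the columns were not median-centred. Spot intensities were not used here, so signal over background is unknown.

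Each column held 1 value that was repeated in 219 to 375 probes, against at most 9 for the next most repeated value. These cells, 2707 in all, were treated as missing. The 120 and 240 min columns were identical and entered once, at their midpoint of 180 min. The design written before the data were examined counted 7 arrays and asked for a value on 6 of them. With 6 distinct arrays, rows with a value on at least 5 were kept. This departure followed from the repeated column.

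Of the 14080 probes, 11304 had 1 gene symbol in the platform annotation, 446 several and 2330 none. Symbols of 11282 probes were matched by gene identifier to a reference gene table, and 0 needed updating. Probes of a gene were averaged, 1642 genes having more than 1 probe, and probes without a single symbol stayed as their own rows. This gave 11763 rows, of which 11377 were tested, 8917 of them named genes.

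For each row limma 3.58.1 (R 4.3.3) fitted a mean and a slope in hours, centred on the mean time, with lmFit and eBayes, leaving 4 residual degrees of freedom per complete row. Benjamini-Hochberg adjusted p-values below 0.05 were called, separately for mean and slope. Gene lists, 29 in number, were fixed before the data were examined. Lists with at least 5 measured members, 27 of them, were tested with camera at a preset correlation of 0.01 on the 11280 rows with values on all 6 arrays, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation. Named genes followed a rule fixed in advance: the 10 highest and 10 lowest means past the threshold with the same sign on every array, the 10 highest and 10 lowest slopes past the threshold, the 5 highest and 5 lowest at 0 min with a self-self log2 ratio within 0.5 of 0, up to 4 members per list with the smallest p, and every measured member of the truncating mutation list. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

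The fit was tested on simulated data with 200 changed rows among 11377. It recovered 95.5% of mean changes of 0.5, 99.5% of those of 1 and 100% of those of 2 on the log2 scale, with 5.0%, 3.4% and 9.1% of calls false. Slopes of 0.25 per hour were recovered in 98.5% and slopes of 0.5 in 100%, with 3.4% and 4.8% of calls false, while slopes of 0.1 were recovered in 0%. The simulated noise was independent between rows and arrays, and far fewer rows were changed than were called in the data. These rates therefore do not carry over to the real fit, whose 2513 called slopes had a median absolute value of 0.10.

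Alternatives fixed in advance were stricter and looser filters, median centring, quantile normalization, 1 row per probe, robust eBayes, subtraction of the self-self log2 ratio, no time covariate, time as rank or as log2 of 1 plus hours, other fold thresholds, leaving out each array, sign patterns of the arrays and random orders of the arrays. With 6 distinct arrays there were 32 sign patterns. Added after the data were seen were the repeated column at 120 min, at 240 min or counted as 2 arrays, the fill values kept, the mean without rows at 0.5 or more from 0 on the self-self array, quantile normalization and left-out arrays for the correlation of mean with slope, self-self subtraction for genes named at 0 min, and camera with an estimated correlation under median centring, self-self subtraction and left-out arrays.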

Results

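RNA from DU 145 cells, an established human prostate cancer line, was compared on 8 deposited arrays. The cells had been kept for 10 h with or without emetine, an inhibitor of translation, at 100 µg/ml. Actinomycin D, which stops transcription, was then added at 5 µg/ml, and cells were harvested 0, 10, 30, 60, 120, 240 and 480 min later. Each of these 7 time points had 1 array of emetine-treated against untreated RNA, and an additional 0 min array carried emetine-treated RNA in both channels (the self-self array). Blocking translation also blocks nonsense-mediated mRNA decay (NMD), the pathway that removes transcripts with premature stop codons, and this pairing of inhibitors is known from screens for such transcripts.

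The columns deposited for 120 and 240 min held identical values in all 14080 probes and were counted as 1 array, which left 6 distinct arrays of emetine against untreated RNA. Which of the 2 times it belongs to is unknown, so it was placed at 3 h. There were no replicates at any time point. The fit's p-values therefore measure scatter around a straight line in time over the 6 arrays of 1 experiment, which may be technical, and the number of arrays limits the precision. The labels do not state which channel was divided by which. Positive values were taken as likely higher with emetine, first because the labels list emetine-treated RNA as channel 1. That order is weak support, since untreated RNA was in Cy5 and a ratio of Cy5 over Cy3 would have the opposite direction. The other reason is that immediate early genes, which are known to be superinduced when translation is blocked, were mostly positive. Of 36 measured members 23 had a positive and 7 a negative mean past the threshold. If the ratio is the other way round, higher and lower with emetine change places throughout. Those genes are accordingly no evidence of their own direction.

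Among named genes past the threshold with the same sign on every array, the chemokine gene CCL20 had the highest ratio averaged over the 6 arrays. It was likely 53-fold higher with emetine (log2 ratio 5.73 ± 0.33, ± giving the SE of the fit throughout). CXCL8, encoding interleukin-8, was likely 43.8-fold higher (5.45 ± 0.19). The ephrin gene EFNA1 had a log2 ratio of 5.22 ± 0.14, and TNFAIP3, an inhibitor of NF-κB signalling, one of 4.87 ± 0.12. They were followed by the stress transcription factor ATF3 (4.75 ± 0.15), the exchange factor MCF2 (4.54 ± 0.093), TRAF1 (4.36 ± 0.096), the cyclin L1 gene CCNL1 (4.13 ± 0.11), the chromatin remodeller CHD2 (4.05 ± 0.096) and interleukin-6, IL6 (4.01 ± 0.25). These 10 genes were positive on 6 of 6 arrays, with limma adjusted p-values between 9.61e-08 (TNFAIP3) and 2.24e-06 (IL6).

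The lowest ratio under the same conditions was that of MAT2A, which encodes the enzyme making S-adenosylmethionine and was likely 7.60-fold lower with emetine (log2 ratio -2.93 ± 0.073). DPH3 (-2.46 ± 0.12), the constitutive chaperone gene HSPA8 (-2.37 ± 0.086), MALL (-2.36 ± 0.058) and the collagen-binding integrin ITGA2 (-2.29 ± 0.061) came next. EPDR1 stood at -2.24 ± 0.061, the amino acid transporter SLC7A5 at -2.16 ± 0.065, ENDOD1 at -2.10 ± 0.19, the tRNA methyltransferase METTL1 at -2.08 ± 0.064 and LPCAT1 at -2.06 ± 0.078. All 10 were negative on 6 of 6 arrays, with adjusted p-values from 9.9e-08 (MALL) to 2.03e-05 (ENDOD1).

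Among the 11377 rows tested, which are genes or probes without a single symbol, 4506 had a positive and 3725 a negative mean past the limma threshold of 0.05. When each probe's self-self log2 ratio was subtracted, 80.1% of the calls remained with the same sign, whereas 208 rows were called with the opposite sign.

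**Figure D1:**
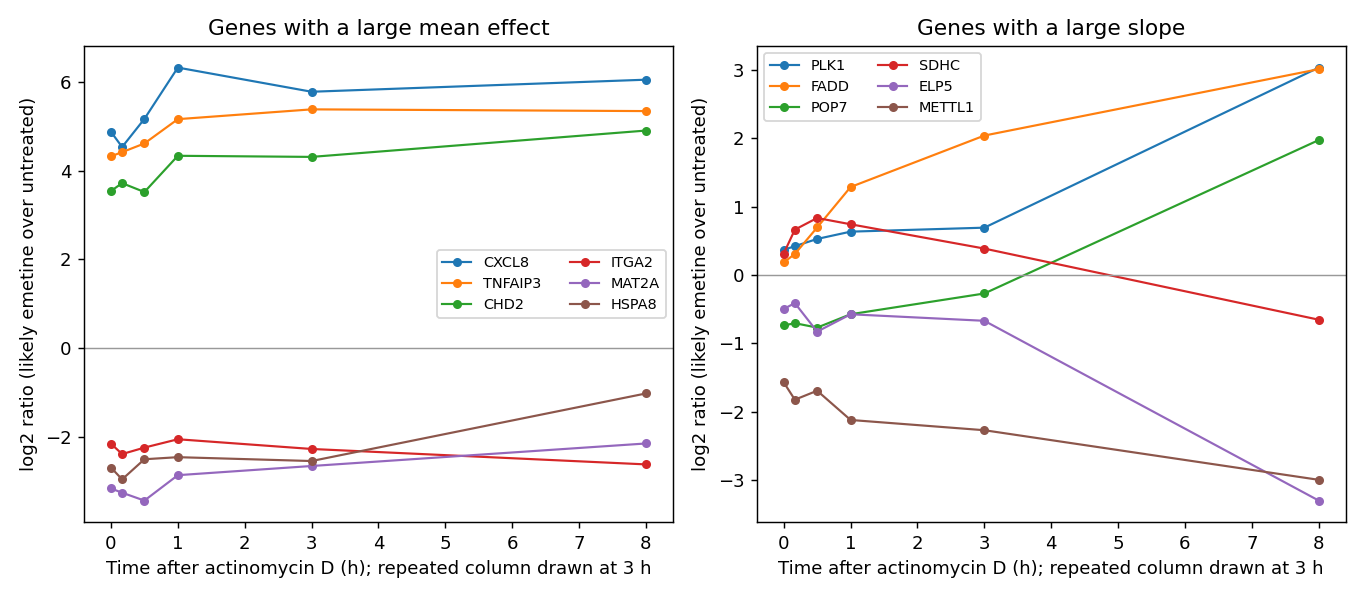
Log2 ratio (likely emetine over untreated, y axis) against hours after actinomycin D (x axis) for 12 named genes, each point being 1 array without replicate and the repeated 120 or 240 min column drawn at 3 h. CXCL8 stayed between 4.53 and 6.32, while PLK1 went from 0.37 at 0 min to 3.04 at 480 min.

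Grouped by lists fixed before the data were examined, the inflammatory and NF-κB targets with short-lived mRNA had higher ratios. In this list 22 of 27 measured members rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 ratio of 1.54. TNFAIP2 (2.99 ± 0.067) and the inhibitor gene NFKBIE (3.34 ± 0.079) rose beside TNFAIP3 and CXCL8. Camera, limma's test of a list against the other rows, gave adjusted p = 8.30e-06, and adjusted p = 0.60 with an estimated correlation. The estimate was 0.17 for this list, against the preset 0.01. Over the tested lists it ran from -0.006 (interferon-stimulated genes) to 0.56 (immediate early genes), with 0.49 for mitotic genes. These estimates rest on 4 residual degrees of freedom. Of the immediate early genes used for the direction, 23 of 36 measured members rose and 7 fell (24 and 8 adjusted over the list alone). ATF3, KLF10 (3.60 ± 0.13) and EGR1 (2.83 ± 0.095) were among those that rose, whereas SRF, a regulator of this class, fell (-0.83 ± 0.048). The list gave adjusted p = 0.0276, and adjusted p = 0.783 with an estimated correlation.

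Mitotic genes also had higher ratios: 30 of 38 measured members rose and 5 fell (30 and 6 adjusted over the list alone). The kinesin KIF2C had a log2 ratio of 1.63 ± 0.069, the checkpoint kinase BUB1B 1.77 ± 0.076 and the spindle protein gene NUSAP1 1.35 ± 0.058. Their median was 0.94, and camera gave adjusted p = 5.81e-05, and adjusted p = 0.724 with an estimated correlation. Without the 480 min array 3 members fell. Among the zinc finger (ZNF) genes, many of which encode transcriptional repressors, 86 of 123 measured members rose and 16 fell (87 and 16 adjusted over the list alone). ZNF140 (2.30 ± 0.077) and ZNF638 (1.93 ± 0.053) were examples, the median was 0.57, and camera gave adjusted p = 3.82e-05, and adjusted p = 0.724 with an estimated correlation.

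Cytosolic ribosomal protein and oxidative phosphorylation genes had lower ratios. Of the cytosolic ribosomal proteins 6 of 53 measured members rose and 42 fell (6 and 43 adjusted over the list alone), among them RPL26 (-1.55 ± 0.049), RPL31 (-1.32 ± 0.046) and RPS20 (-1.21 ± 0.048). RPL17 went the other way (1.57 ± 0.057). Their median was -0.81, with adjusted p = 3.14e-09, and adjusted p = 0.60 with an estimated correlation. Probes for these genes can also bind transcripts of their many processed copies. Of the oxidative phosphorylation genes 7 of 71 measured members rose and 58 fell (7 and 58 adjusted over the list alone), including the complex I subunits NDUFB9 (-1.41 ± 0.055) and NDUFB2 (-1.25 ± 0.051) and the ATP synthase subunit ATP5MC1 (-1.22 ± 0.051). The median was -0.66, with adjusted p = 7.03e-11, and adjusted p = 0.60 with an estimated correlation. Part of both shifts was present when the same RNA was in both channels: on the self-self array the median was -0.32 for ribosomal proteins and -0.39 for oxidative phosphorylation. After subtraction of that array the medians were -0.38 (adjusted p = 3.72e-06, and adjusted p = 0.618 with an estimated correlation) and -0.24 (adjusted p = 3.82e-04, and adjusted p = 0.618 with an estimated correlation).

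Housekeeping genes, the class on which the authors' normalization rested per the labels, had a median of -0.60. In this list 2 of 15 measured members rose and 11 fell (2 and 11 adjusted over the list alone), with SDHA at -0.99 ± 0.058, PGK1 at -0.88 ± 0.054 and HPRT1 at -0.74 ± 0.049, and camera gave adjusted p = 0.00477, and adjusted p = 0.60 with an estimated correlation. Without the 0 min, 60 min, 120 or 240 min, or 480 min array 1 member rose. Which genes the authors used is not given in the sources used here. Of the epithelial cytoskeleton and adhesion genes 5 of 28 measured members rose and 19 fell (5 and 19 adjusted over the list alone), including ITGA2 and the keratin gene KRT8 (-1.12 ± 0.066), with adjusted p = 0.00637, and adjusted p = 0.724 with an estimated correlation. Of the glycolysis and hypoxia genes 4 of 24 measured members rose and 15 fell (4 and 15 adjusted over the list alone). LDHB was lower (-0.94 ± 0.054) and the peptide hormone gene ADM higher (2.44 ± 0.072), and the list gave adjusted p = 0.0207, and adjusted p = 0.724 with an estimated correlation. Of the proteasome subunits 9 of 34 measured members rose and 19 fell (9 and 19 adjusted over the list alone), with PSMB10 at -1.27 ± 0.050 and PSMB4 at -1.19 ± 0.053, and adjusted p = 0.0430, and adjusted p = 0.783 with an estimated correlation. The calls of these last 3 lists ended when the self-self array was subtracted (adjusted p = 0.0958, 0.0857 and 0.395). Their medians went from -0.31, -0.36 and -0.22 to -0.091, -0.20 and -0.071. The proteasome call also ended without the 120 or 240 min array (median -0.17, adjusted p = 0.0829).

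**Figure D2:**
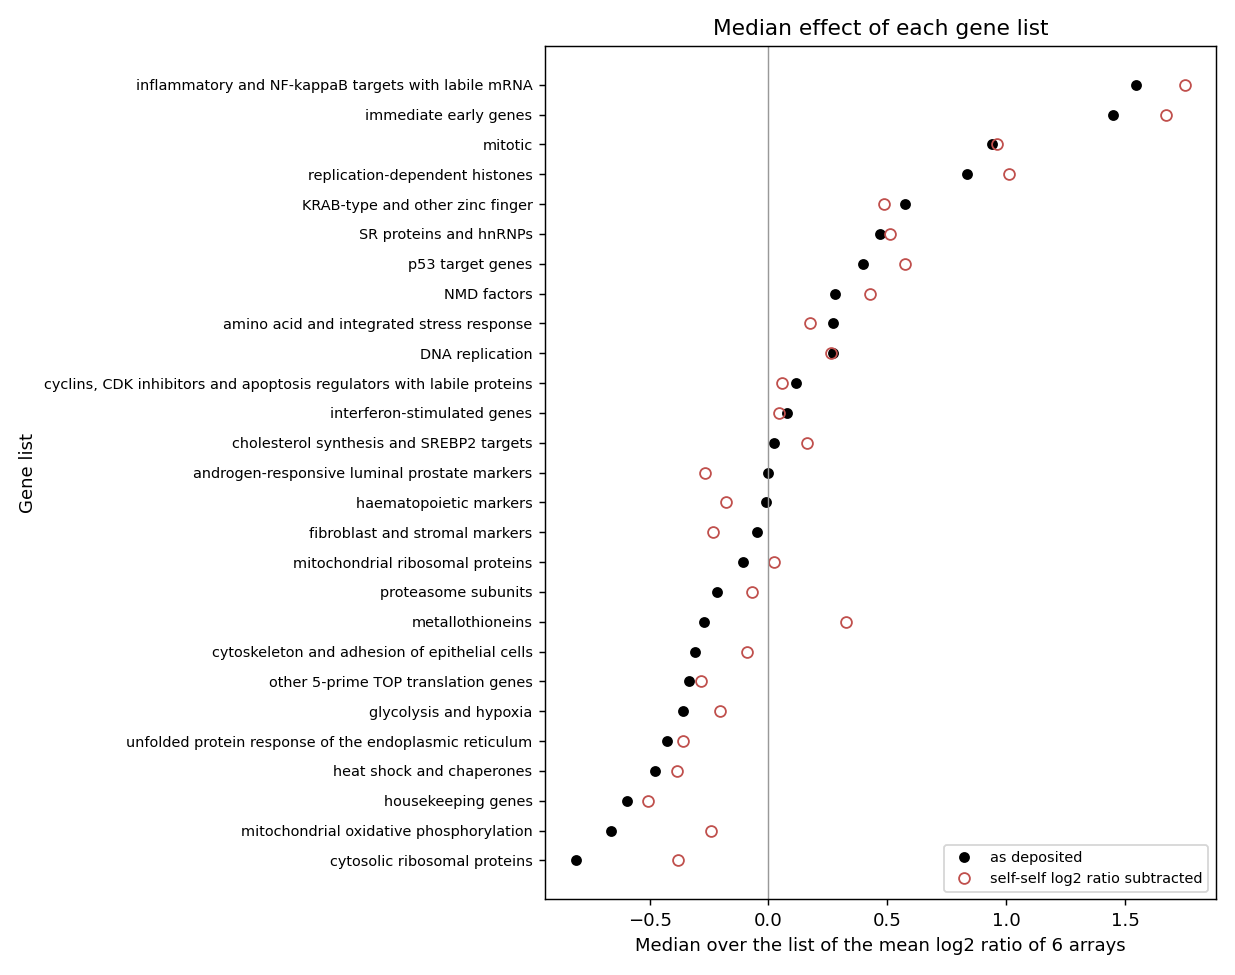
Median over each gene list (y axis) of the log2 ratio averaged over 6 arrays (x axis), as deposited (filled points) and after subtraction of the self-self log2 ratio (open points). The inflammatory list lies at 1.54 and 1.75, while the metallothioneins change sign, from -0.27 to 0.33.

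Genes tied to NMD were mixed. Of the NMD factors 11 of 19 measured members rose and 4 fell (11 and 4 adjusted over the list alone). SMG8 (1.55 ± 0.077), SMG9 (1.27 ± 0.058), UPF2 (0.97 ± 0.054) and the exon junction partner RNPS1 (0.77 ± 0.054) rose, and the list was not called (adjusted p = 0.231). Of the splicing factors, several of which control their own mRNA through exons that trigger NMD, 18 of 30 measured members rose and 8 fell (18 and 8 adjusted over the list alone), and this list was not called either (adjusted p = 0.0732). Without the 0 min or 10 min array 5 of them fell. PTBP2 was 6.93-fold higher (2.79 ± 0.066), CLK1 stood at 1.49 ± 0.054 and SRSF3 at 1.45 ± 0.063, whereas HNRNPAB fell (-1.49 ± 0.054). Of the 4 measured host genes of small nucleolar RNAs, too few for a list test, SNHG1 (1.17 ± 0.072) and DANCR (0.74 ± 0.064) rose and SNHG3 fell (-0.29 ± 0.11). The SNHG3 call ended without the 0 min, 10 min or 30 min array (log2 ratio -0.17, -0.21 and -0.27). EPB41L4A-AS1 had a value of 0.068 ± 0.084 (adjusted p = 0.489), and -0.23 after subtraction of the self-self array. Among genes known to carry truncating mutations in DU 145, the 2 measured were RB1, which rose (0.41 ± 0.055, adjusted p = 0.000203), and BAX, which did not pass (0.20 ± 0.12, adjusted p = 0.18) but did without the 30 min array (log2 ratio 0.36) and after subtraction of the self-self array (0.57). Positive calls were common, with 4506 among all 11377 rows tested. Their share was higher among the NMD factors and the splicing factors, but camera called neither list as deposited. The splicing factor list was called after subtraction of the self-self array, though not with an estimated correlation. Whether genes tied to NMD stand apart is therefore not settled.

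The amino acid and integrated stress response list held strong changes both ways and was not called: 17 of 32 rose and 11 fell (17 and 11 adjusted over the list alone, adjusted p = 0.521). ATF3, the cell cycle inhibitor CDKN1A (1.90 ± 0.087) and the seryl-tRNA synthetase SARS1 (1.48 ± 0.068) rose while SLC7A5 fell. For unfolded protein response genes, 6 of 16 rose and 10 fell (6 and 10 adjusted over the list alone, adjusted p = 0.201). DDIT3 was higher (2.62 ± 0.13), and PDIA4 (-1.27 ± 0.065) and SEC61B (-0.99 ± 0.050) were lower. Most of the SEC61B value was present with the same RNA in both channels (-0.80 on the self-self array). For chaperones, 6 of 21 rose and 13 fell (6 and 13 adjusted over the list alone, adjusted p = 0.0638), with HSPA8 and FKBP4 (-1.21 ± 0.051) lower and DNAJB4 higher (2.05 ± 0.099). For replication-dependent histones, 11 of 17 rose and 2 fell (11 and 2 adjusted over the list alone, adjusted p = 0.0638), with H2BC5 at 1.44 ± 0.073, H1-3 at 1.25 ± 0.058 and H2BC21 at -0.99 ± 0.049. For DNA replication genes, 19 of 33 rose and 8 fell (19 and 9 adjusted over the list alone, adjusted p = 0.147), with ORC1 at 1.43 ± 0.051 and MCM2 at 1.26 ± 0.061. Among p53 targets, in a line with mutant p53, 12 of 19 rose and 3 fell (12 and 3 adjusted over the list alone, adjusted p = 0.0638), with TNFRSF10B at 2.34 ± 0.083, BBC3 at 2.07 ± 0.098 and XPC at 1.91 ± 0.083. For cyclins, CDK inhibitors and apoptosis regulators, 7 of 19 rose and 7 fell (7 and 7 adjusted over the list alone, adjusted p = 0.915), with BIRC2 at 2.46 ± 0.095 and PMAIP1 at 2.21 ± 0.092. For other translation genes with 5' TOP motifs, 4 of 17 rose and 11 fell (4 and 11 adjusted over the list alone, adjusted p = 0.0732), with EIF3F at -1.33 ± 0.075 and NPM1 at -0.90 ± 0.063. For mitochondrial ribosomal proteins, 9 of 43 rose and 21 fell (9 and 21 adjusted over the list alone, adjusted p = 0.0638), with MRPL18 at -1.83 ± 0.081 and MRPS31 at 1.34 ± 0.072. For metallothioneins, 0 of 5 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.0708), among them MT2A (-0.27 ± 0.051) and MT1G (-0.29 ± 0.052), a direction that turned when the self-self array, on which MT2A stood at -0.72, was subtracted (median -0.27 before and 0.33 after). Without the 60 min or the 120 or 240 min array 3 metallothioneins fell, and without the 480 min array the median, which was that of MT2A, was -0.17. For cholesterol synthesis genes, 5 of 15 rose and 5 fell (5 and 5 adjusted over the list alone, adjusted p = 0.915). MVK stood at 1.08 ± 0.052 and PMVK at -0.67 ± 0.054, with PMVK at -0.49 on the self-self array. This list had no settled direction: its median was 0.022 with a negative direction in camera, -0.026 with each array centred on its median, and 0.16 with a positive direction after subtraction of the self-self array, when 7 members rose and 3 fell. It was 0.040 without the 10 min array, -0.00011 without the 60 min array, and 0.040 with a positive direction without the 120 or 240 min array. With an estimated correlation camera called none of the 27 tested lists. After subtraction of the self-self array the splicing factor list was called (median 0.51, adjusted p = 0.0384, and adjusted p = 0.618 with an estimated correlation), as was DNA replication (median 0.26, adjusted p = 0.0384, and adjusted p = 0.618 with an estimated correlation), while the median of the mitochondrial ribosomal proteins turned to 0.023. Without the 480 min array the histones were called (median 0.86, adjusted p = 0.0419, and adjusted p = 0.608 with an estimated correlation), as were the mitochondrial ribosomal proteins (median -0.13, adjusted p = 0.0342, and adjusted p = 0.774 with an estimated correlation).

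How far the ratios lay from 1 was counted on each array without a test. On the self-self array 40 rows were at least 2-fold from 1. At 0 min there were 1018 rows at least 2-fold above 1, likely higher with emetine, and 295 at least 2-fold below 1. At 480 min the counts were 2141 and 1026. In between, 1005 and 380 rows passed at 10 min, 1213 and 370 at 30 min, 1562 and 423 at 60 min, and 1387 and 685 in the 120 or 240 min column. The SD of the log2 ratios was 0.30 on the self-self array, 0.66 at 0 min and 1.04 at 480 min. The 5 highest named genes at 0 min with a self-self value within 0.5 of 0 were CXCL8 (4.87), EFNA1 (4.46), TNFAIP3 (4.32), ATF3 (4.18) and MCF2 (4.10). Of the 5 lowest, MAT2A (-3.17), HSPA8 (-2.70) and CEACAM1 were negative on all 6 arrays of emetine against untreated RNA. CEACAM1 was near 0 at 10 min (-0.11) and 30 min (-0.024). DAO (-4.14), CDK5RAP2 (-3.67) and CEACAM1 (-2.60) had means over the arrays of -0.59 ± 0.55, -0.17 ± 0.54 and -0.67 ± 0.32, none past the threshold (adjusted p = 0.353, 0.786 and 0.0882). These means rested on the 0 min array. Without it DAO had a mean of 0.12 that did not pass (limma adjusted p = 0.362), while CDK5RAP2 at 0.53 (adjusted p = 2.98e-04) and CEACAM1 at -0.29 (adjusted p = 0.00441) passed.

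**Figure D3:**
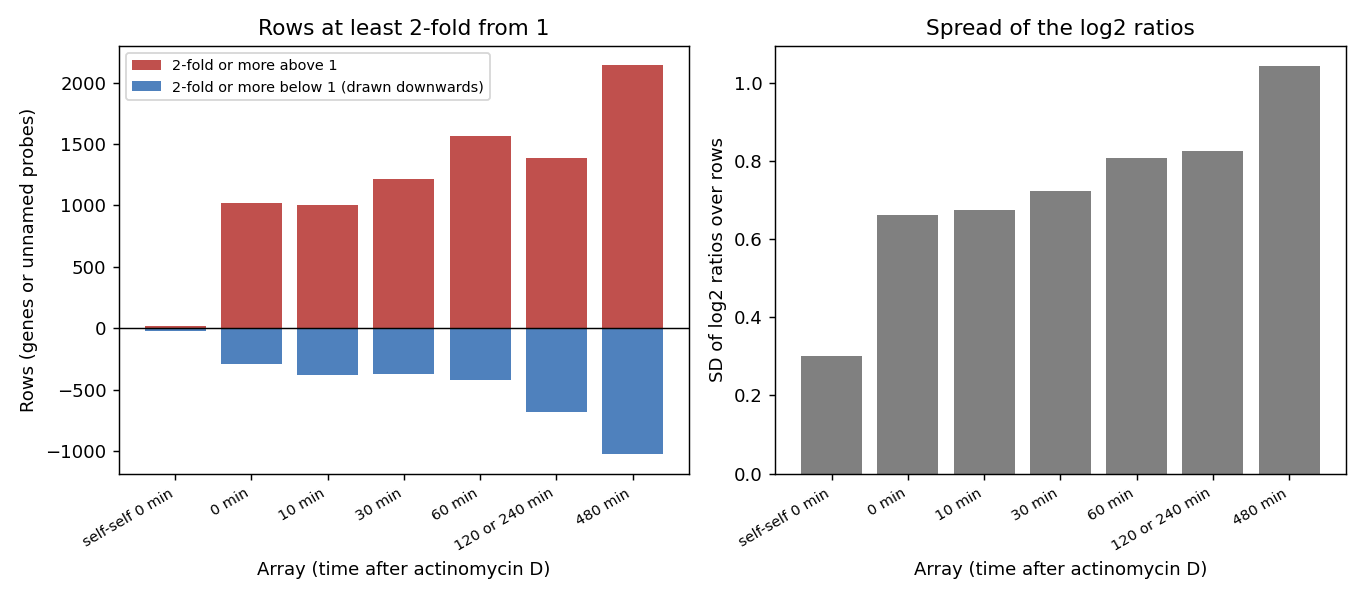
Left, number of rows (y axis) at least 2-fold above 1 (upwards) or below 1 (downwards) on each of 7 distinct arrays (x axis). Right, SD of the log2 ratios (y axis) on the same arrays, which was 0.30 on the self-self array and 1.04 at 480 min.

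After transcription stops, a difference in mRNA decay between treated and untreated cells changes the log2 ratio with time. The slope of the fit measures any change of that ratio, relative to the normalization of each slide. It is therefore not by itself a difference in decay. Among named genes with a slope past the threshold, the steepest rise was that of SCGB2A1, a secretoglobin. Its slope was 0.42 ± 0.034 log2 per hour, from 1.16 at 0 min to 4.70 at 480 min. MAD2L1BP (0.37 ± 0.044), the centromere chaperone HJURP (0.37 ± 0.037), AMOTL2 (0.36 ± 0.079), SLN (0.35 ± 0.054) and OSGIN1 (0.34 ± 0.034) followed. POP7 went from -0.74 to 1.97, and PSG7, YJU2 and the death-domain adaptor FADD completed the 10 highest. On the self-self array POP7 stood at -0.69, so its negative start was about that seen with the same RNA in both channels. The steepest fall among such genes was that of ELP5 (-0.34 ± 0.045), then TAF10 (-0.23 ± 0.025), BSCL2 (-0.20 ± 0.019), PDE6G (-0.17 ± 0.047) and asparagine synthetase, ASNS (-0.17 ± 0.032). NME2, METTL1, ARPC1A, SDHC and NFE2L1 had slopes of -0.16 each, and PSG7, YJU2 and FADD of 0.34. Adjusted p-values of these 20 genes lay between 0.00165 (SCGB2A1) and 0.0393 (PDE6G). None of the 20 calls held without the 480 min array: the slopes that moved by over 1.5 times were 0.61 for MAD2L1BP, 0.80 for AMOTL2, 0.57 for SLN, 0.16 for POP7, 0.14 for PSG7, 0.16 for YJU2 and 0.61 for FADD on the rising side and -0.048 for ELP5, -0.10 for TAF10, -0.13 for BSCL2, -0.053 for SDHC and -0.083 for NFE2L1 on the falling side, while ASNS turned to 0.012.

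In all, 1492 rows had a positive and 1021 a negative slope past the limma threshold. These calls rested on the 480 min array, the one farthest in time: without it limma called 0 rows, against 1982 at an unadjusted p under 0.05. The estimates mostly kept their direction: of the 2513 called slopes, 157 had the opposite sign without that array, and the slopes of all rows with and without it had an r of 0.60. Median slopes without it were -0.12 for ribosomal proteins (against -0.052 with it), -0.10 for oxidative phosphorylation (-0.061), 0.098 for zinc finger genes (0.050) and 0.037 for mitotic genes (0.060), over 5 arrays with a shorter span of time. After quantile normalization, which gives all arrays the same distribution, 259 rows had a positive and 57 a negative slope past the threshold, a positive share of 82.0% against 59.4%. With time as rank order the counts were 604 and 107. Without the 0 min, 10 min or 30 min array the negative count was 447, 441 or 530, and without the 10 min array the positive count was 986.

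Among mitotic genes 17 of 38 measured members rose and 1 fell (17 and 4 adjusted over the list alone), with the kinase PLK1 at 0.32 ± 0.035 per hour, CKS2 at 0.25 ± 0.026 and KIF23 at 0.24 ± 0.032. Camera gave adjusted p = 5.49e-04, and adjusted p = 0.752 with an estimated correlation, and without the 480 min array the call ended (adjusted p = 0.328). Among zinc finger genes 35 of 123 measured members rose and 4 fell (36 and 5 adjusted over the list alone), with ZNF22 at 0.25 ± 0.025 and ZNF330 at 0.20 ± 0.021, and adjusted p = 4.41e-04, and adjusted p = 0.752 with an estimated correlation. Of the oxidative phosphorylation genes 1 of 71 measured members rose and 33 fell (2 and 46 adjusted over the list alone), with NDUFA1 at -0.099 ± 0.017 and ATP5PF at -0.10 ± 0.017, and adjusted p = 1.26e-11, and adjusted p = 0.680 with an estimated correlation. Of the ribosomal proteins 5 of 53 measured members rose and 21 fell (5 and 25 adjusted over the list alone). RPL31 (-0.13 ± 0.017) and RPS20 (-0.11 ± 0.017) fell while RPL28 rose (0.32 ± 0.052), with adjusted p = 2.65e-06, and adjusted p = 0.752 with an estimated correlation. Of the housekeeping genes 0 of 15 measured members rose and 6 fell (0 and 8 adjusted over the list alone), HPRT1 at -0.099 ± 0.017 and PGK1 at -0.098 ± 0.019, with adjusted p = 0.00129, and adjusted p = 0.680 with an estimated correlation. Of the glycolysis and hypoxia genes 0 of 24 measured members rose and 3 fell (0 and 3 adjusted over the list alone), LDHB at -0.095 ± 0.019, with adjusted p = 0.00999, and adjusted p = 0.752 with an estimated correlation. Of the metallothioneins 0 of 5 measured members rose and 3 fell (0 and 4 adjusted over the list alone), MT2A at -0.080 ± 0.018 and MT1G at -0.064 ± 0.018, with adjusted p = 0.0335, and adjusted p = 0.752 with an estimated correlation. That call ended without the 480 min array (adjusted p = 0.0720, median slope -0.071) and without the 10 min array (adjusted p = 0.0657, median slope -0.057), against a median of -0.059 with all arrays. Without the 480 min array no member of any list passed, and the slopes that moved by over 1.5 times were 0.097 for PLK1, 0.11 for CKS2, 0.13 for KIF23, 0.54 for RPL28 and -0.15 for PGK1. Median slopes without it were -0.10 for housekeeping genes (against -0.061 with it) and -0.060 for glycolysis genes (-0.035). The counts also moved without other arrays. Without the 0 min, 10 min or 30 min array 9, 6 or 9 ribosomal proteins and 21, 16 or 21 oxidative phosphorylation genes fell. Without the 10 min array 2 ribosomal proteins and 21 zinc finger genes rose, and without the 0 min array 1 zinc finger gene fell. Mitotic genes that rose numbered 11 without the 0 min and 11 without the 10 min array, and the 1 that fell was lost without the 0, 10, 30 or 60 min array. Metallothioneins that fell numbered 1 without the 0, 30 or 60 min array and 0 without the 10 min array, and oxidative phosphorylation genes that rose 2 without the 60 min array. No slope was adjusted for the self-self array, where oxidative phosphorylation, ribosomal protein and metallothionein genes had medians of -0.39, -0.32 and -0.52. The regression coefficient on that array was 0.727 at 0 min, 0.946 at 10 min, 0.721 at 30 min and 0.973 at 60 min. It was 1.305 in the repeated column and 1.285 at 480 min. A dye bias that was larger on the later arrays would give such lists falling slopes, and its share was not tested.

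The other 20 tested lists were not called for the slope (adjusted p from 0.0582 to 0.976), but some of their members changed. CDKN1A rose at 0.28 ± 0.031 per hour, the NMD cofactor PNRC2 at 0.30 ± 0.053, the splicing kinase CLK3 at 0.24 ± 0.036, SRSF4 at 0.15 ± 0.022 and MRPS30 at 0.28 ± 0.027. Several genes with a negative log2 ratio at 0 min rose: the matricellular protein gene CCN2 went from -1.02 to 1.39, cyclin E1 (CCNE1) from -0.84 to 0.98, the inducible chaperone HSPA1B from -1.28 to 0.62 and HSPA8 from -2.70 to -1.03. None of these calls held without the 480 min array, where the slope was 0.17 for MRPS30 and went from 0.21 to 0.074 for HSPA8. Without the 480 min array, camera with the preset correlation called 5 of these lists. Those upwards were immediate early genes (median slope 0.23 against 0.022, adjusted p = 5.46e-06, and adjusted p = 0.618 with an estimated correlation) and inflammatory targets (median slope 0.13 against 0.039, adjusted p = 0.0126, and adjusted p = 0.618 with an estimated correlation). Those downwards were proteasome subunits (median slope -0.081 against -0.021, adjusted p = 3.61e-05, and adjusted p = 0.465 with an estimated correlation), histones (median slope -0.11 against -0.031, adjusted p = 0.00316, and adjusted p = 0.465 with an estimated correlation) and epithelial genes (median slope -0.068 against -0.029, adjusted p = 0.0126, and adjusted p = 0.547 with an estimated correlation). The histones were also called without the 30 min (adjusted p = 0.0372, and adjusted p = 0.870 with an estimated correlation) or 60 min array (adjusted p = 0.0477, and adjusted p = 0.647 with an estimated correlation). Across the 11377 rows, mean and slope had a Pearson r of 0.56 and a Spearman rho of 0.57, a description over rows that are not independent replicates. After quantile normalization r was -0.047, and without the 480 min array it was 0.37.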

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

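Of the tests in this part, the one of the 480 min array alone and the count over the orders that kept this array last were chosen after the result was seen. What drew attention is that the emetine effect differed between time points by a test, the slope of the fit: 1492 rows had rising and 1021 falling ratios. The named slopes, in log2 per hour, were 0.42 for SCGB2A1, 0.37 for MAD2L1BP, 0.37 for HJURP, 0.36 for AMOTL2, 0.35 for SLN, 0.34 for OSGIN1, 0.34 for POP7, 0.34 for PSG7, 0.34 for YJU2 and 0.34 for FADD. On the falling side they were -0.34 for ELP5, -0.23 for TAF10, -0.20 for BSCL2, -0.17 for PDE6G, -0.17 for ASNS, -0.16 for NME2, -0.16 for METTL1, -0.16 for ARPC1A, -0.16 for SDHC and -0.16 for NFE2L1. Without the 480 min array limma called 0 slopes, against 1982 at an unadjusted p under 0.05, and the slopes that moved by over 1.5 times were 0.61 for MAD2L1BP, 0.80 for AMOTL2, 0.57 for SLN, 0.16 for POP7, 0.14 for PSG7, 0.16 for YJU2 and 0.61 for FADD on the rising side and -0.048 for ELP5, -0.10 for TAF10, -0.13 for BSCL2, -0.053 for SDHC and -0.083 for NFE2L1 on the falling side, while ASNS turned to 0.012.

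For the mean, 1 of 32 sign patterns of the arrays, the real one included, gave as many calls as the real 8231, the highest other giving 2340. The pattern with 2340 turned the sign of the 480 min array alone. This count shows that the arrays share their signs. It cannot exclude chance, because the arrays are time points of 1 experiment without replicate or dye swap. A dye bias or a difference between cultures common to all arrays would pass it as well. For the slope, 1 of 100 orders of the 6 arrays in time, the real one included, gave as many rows as the real 2513, and the highest other order gave 2326. This count rests on the place of the 480 min array, since orders that did not keep it last called at most 2 rows. Of the 18 orders that kept it last, the real one included, 5 wrong ones called 2326, 1654, 1610, 1545 and 1413 rows and 1 called 202. Only the real one reached 2513. With 18 orders, the real one included, the share cannot be lower than 1 in 18, so it could not go under 0.05. The count therefore cannot decide on chance for the order of the other 5 arrays.

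The pattern behind many slopes is that ratios spread further from 1 with time after actinomycin D, the SD rising from 0.66 at 0 min to 1.04 at 480 min. The tables argue against growing noise that differs between probes of a gene as the main source. The growth in variance between such probes was 39.4% of that over genes (bootstrap interval over genes 31.6 to 47.9). Noise common to the probes of a gene on an array cannot appear in this measure, so it stays open. After regression on the self-self array 85.8% of the growth in variance was left. This does not exclude dye bias, because noise on that 1 array weakens the regression. The regression coefficient of the emetine array on it was 0.727 at 0 min, 0.721 at 30 min, 1.305 in the repeated column and 1.285 at 480 min. A dye bias that grew with time therefore stays open. Such a coefficient also rises with the spread of the array, and Pearson r over probes was 0.33 at 0 min and 0.37 at 480 min. The tables also argue against the 480 min array alone, since the SD was already 0.83 in the repeated column. The SDs of the other 5 arrays followed their order in time, as 1 of the 120 orders of these arrays does (an exact permutation test, 1-sided). That order had been seen when the test was chosen, so the count restates it. Differences in mRNA decay between treated and untreated cells stay open and were not tested separately, because levels in each channel were not used here.

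For the slopes of single genes, a stretch of all ratios by a common factor on the later arrays stays open. After quantile normalization 11.2% of the 2513 calls were left with the same sign. Their median absolute slope went from 0.10 to 0.055 log2 per hour with a median SE of 0.021 before and 0.021 after, so the calls ended because the slopes shrank, and 97.1% of the slopes kept their sign. A stretch can be technical, such as a change in the linear range of the scan, or biological, such as decay that widens existing differences, and these were not told apart.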

How the results depend on the processing

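Alternatives added after the data were seen are the repeated column at 120 min, at 240 min or as 2 arrays, the fill values, the rows off 0 on the self-self array, quantile normalization and left-out arrays for the correlation, the self-self subtraction at 0 min, and the estimated correlation under the alternatives for lists. The counts of rows with a called mean stayed within 1.5 times under every alternative, and 87 of the 97 named means kept direction and side of the threshold in all of their alternatives. Subtracting the self-self log2 ratio turned the metallothioneins MT1H (0.23), MT1G (0.38), MT2A (0.45) and MT3 (0.33) and the host gene EPB41L4A-AS1 (-0.23), whose value ranged from -0.0035 to 0.12 when arrays were left out in turn. Among genes named at 0 min, the mean ranged likewise from -0.83 to 0.12 for DAO, -0.35 to 0.53 for CDK5RAP2 and -0.80 to -0.29 for CEACAM1, the highest values being without the 0 min array.

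The slopes depended on the processing. Rising and falling counts were 259 and 57 with quantile normalization and 604 and 107 with time as rank order, and ranged from 0 to 1632 and from 0 to 1034 when arrays were left out in turn, the 0 being without the 480 min array. None of the 44 named slopes kept its call without that array, but 43 kept their direction, the exception being ASNS, which ranged from -0.19 to 0.012. With quantile normalization 21 lost the call, with time as rank order 25 did, and none turned in either. The correlation of mean with slope was 0.60 over rows with a called mean, 0.59 with time as rank order, 0.37 to 0.59 with arrays left out and -0.047 with quantile normalization. The cause was not tested, apart from the stretch weighed above. Lists called up and down numbered 4 and 6 for the mean and 2 and 5 for the slope. With arrays left out in turn they ranged from 4 to 5 and 5 to 7 for the mean and from 2 to 3 and 4 to 7 for the slope. The numbers were 0, 0, 0 and 0 with an estimated correlation, as also under median centring, self-self subtraction (mean) and each left-out array.

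Rows at least 1.5-fold from 1 numbered 442 on the self-self array, 3408 at 0 min, 3495 at 10 min, 3801 at 30 min, 4197 at 60 min, 4661 in the repeated column and 5506 at 480 min, and rows at least 3-fold from 1 numbered 14, 316, 358, 503, 712, 673 and 1398, as other thresholds must give. With rows measured on all arrays the self-self array had 10. Leaving out the repeated column is among the left-out arrays. No paired analysis was possible because each group has 1 array. Signal over background, which limits faint spots, is unknown.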

Other observations

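Both tests of the self-self array in this part were chosen after the result was seen. Markers of luminal prostate, haematopoietic and stromal cells had median log2 ratios of -0.00073, -0.0097 and -0.049 as deposited and of -0.27, -0.18 and -0.23 after subtraction of the self-self array, when 7, 15 and 14 members fell and 1, 2 and 2 rose. The medians as deposited depended on single arrays: without the 0, 10, 30, 60, 120 or 240, and 480 min array in turn they were 0.0079, 0.00023, 0.0048, 0.0086, -0.041 and -0.0083 for luminal, -0.025, -0.017, 0.026, -0.0056, -0.064 and -0.034 for haematopoietic and -0.033, -0.047, -0.028, -0.047, -0.11 and -0.012 for stromal markers. For androgen-responsive luminal prostate markers, 2 of 10 rose and 2 fell (2 and 2 adjusted over the list alone, adjusted p = 0.842), with FKBP5 at 0.42 ± 0.064 and STEAP1 at -0.43 ± 0.084. For haematopoietic markers, 6 of 25 rose and 10 fell (6 and 10 adjusted over the list alone, adjusted p = 0.333), with CD52 at 1.19 ± 0.071 and CD68 at -0.86 ± 0.057, and after subtraction of the self-self array this list was called with a negative direction (adjusted p = 0.0395, and adjusted p = 0.618 with an estimated correlation, where the preset correlation gave 0.0395 to 0.436 over all alternatives). For fibroblast and stromal markers, 5 of 22 rose and 7 fell (5 and 7 adjusted over the list alone, adjusted p = 0.509), with ACTA2 at -1.19 ± 0.060 and VCAN at 0.99 ± 0.058, and 4 fell without the 480 min array. Without that array 1 luminal marker rose and 1 fell, and without the 60 min array 1 fell. After subtraction the luminal and stromal lists were not called (adjusted p = 0.0857 and 0.0630). Interferon-stimulated genes went both ways: 11 of 24 rose and 9 fell (11 and 9 adjusted over the list alone, adjusted p = 0.915), with IFIT2 at 3.04 ± 0.092, 8.24-fold higher, and OASL at 2.17 ± 0.092.

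The self-self array correlated with the emetine arrays across rows, with Pearson r over probes from 0.31 (30 min) to 0.45 (the repeated column). If one of its channels had carried untreated RNA, as a sentence of its label says, it should track the 0 min array about as the 10 min array does. The tables argue against this: its regression coefficient on the 0 min array was 0.135 (bootstrap interval over genes 0.126 to 0.145), against 0.930 for the 10 min array. A probe-specific dye bias shared by all arrays is a candidate explanation that the values of probes within genes go with. Probes of the same gene largely share the RNA ratio, and their deviations from the mean of the gene on the self-self array recurred on every emetine array. The regression coefficients ran from 0.61 at 0 min (bootstrap interval over genes 0.50 to 0.72) to 1.36 at 480 min. Other values do not go with an offset shared in full. Luminal, haematopoietic and stromal markers had self-self medians of 0.22, 0.12 and 0.18, which did not recur in their medians as deposited. MT2A stood at -0.72 on the self-self array and at -0.0026 at 10 min. Subtraction of that array shifts such genes whether or not the offset is shared.

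Where the repeated column lies in time was not settled by its values. Over 548 rows that differed at least 2-fold between 60 and 480 min, its median position between these arrays was 0.0385, where a straight line gives 0.143 for 120 min and 0.429 for 240 min. The array of known time at 60 min lay at 0.362 between 0 and 480 min, where a straight line gives 0.125.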
